A study of Mus musculus with 441 samples.

How the data were processed

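Single-cell RNA-seq, bulk RNA-seq and ChIP-seq were measured in mouse embryonic stem cells (mESCs). The v6.5 line was grown in serum+LIF or in 2i+LIF, where 2i is a pair of inhibitors of MEK and GSK3. A Dgcr8 knockout line, which lacks a partner of Drosha needed to process most microRNAs, was grown in serum+LIF. Neural precursor cells (NPCs) were derived from v6.5 cells in culture and, per the labels, selected as nestin-positive cells. The cells came from microfluidic C1 chips, with chambers inspected optically per the labels. No caller of doublets was run, and no cell was left out: the planned filter, on cells with fewer detected genes than 50% of the median of their plate, removed 0 cells.

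The submitters' processing notes name Bowtie, RSEM and mouse genome build mm9, without versions or roles. The deposited RNA tables hold the natural log of TPM + 1 (TPM, a length-normalised share of transcripts), as the sums of the values after reversing the log show; the authors' filters and annotation are not given in the sources used here. The deposited ChIP table holds raw read counts in a window of 1000 bases per gene, 1 column per library. The place of the window relative to the gene is not stated, so it is called the window of the gene. TPM keeps no trace of the number of reads, so the depth of the RNA libraries is unknown, and the number of genes detected is given in its place. Names that a spreadsheet had turned into dates were left out (5 of 21001 in the bulk table, 56 of 22443 in the mESC table and 29 of 18873 in the NPC table). Several names can carry identical values, since the tables list some genes under more than 1 name: 2064 of the 10078 genes tested in bulk fell in such groups, 1091 of them redundant, and 2489 of 12394 in the plates, 1308 of them redundant. All columns of the tables were used.

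The following choices were fixed before the data were examined: the groups, comparisons, tests, gene lists, the rule for naming genes and the alternative settings. Samples were grouped by the labels of culture and genotype, and single cells also by plate (from the titles). Cells are not replicates, so cells of a plate were averaged. The bulk fit held 5 libraries (2 serum, 1 2i, 2 knockout) and the plate fit 4 plates (2 serum, 1 2i, 1 knockout), each with 1 mean per group. Both used limma 3.58.1 in R 4.3.3 with a trend, on log2(TPM + 1), for genes with a mean TPM of at least 1. A Benjamini-Hochberg adjusted p under 0.05 was called a change. The fits have 2 and 1 residual degrees of freedom before moderation (prior degrees of freedom in bulk 10.3), and a group of 1 sample is assumed to vary like the pairs. The p-values measure only the spread between these samples, which may be technical. On simulated data shaped like the bulk knockout comparison, with 200 changed genes among 10078, the fit recovered 42% of 2-fold and 95% of 4-fold changes and called 2 unchanged genes.

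Gene lists were tested in bulk with camera (preset correlation 0.01, Benjamini-Hochberg over the lists of a comparison, lists of at least 5 tested genes), and again with an estimated correlation. In that second version no list was called, even where the estimate lay under 0.01. Its p-values alone therefore do not show that genes of a list move together. Camera compares a list with all other genes, so its direction is relative to them. The 28 lists, written from general knowledge, cover core and naive pluripotency, primed and post-implantation epiblast, ERK feedback and immediate targets, Wnt/beta-catenin targets, BMP and Nodal targets, Polycomb-target developmental regulators, primitive endoderm, trophoblast, mesoderm and primitive streak, two-cell-like genes, neural precursor, fibroblast and feeder, germline genes silenced by DNA methylation, DNA methylation machinery, Polycomb machinery, microRNA machinery, known targets of the miR-290/302 seed family, known let-7 targets, G1/S, G2/M, p53 targets, stress and dissociation response, glycolysis, cholesterol and lipid synthesis, imprinted genes, Myc and Mycn and partners, oxidative phosphorylation subunits and cytosolic ribosomal proteins. Counts of members rest on the adjustment over all genes unless stated to be adjusted over the list alone.

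Changes shared by 2i and knockout were described by the correlation and covariance across genes, beside 100 simulations of unchanged groups against the same serum libraries, since shared controls alone give a correlation. Variability between cells was the SD over cells of log2(TPM + 1). Its excess over the running median of 201 genes of like mean level was compared with 10000 random lists matched on level in 20 bins. Co-variation was the mean pairwise Spearman correlation within a list, with 1000 random lists. On simulated data with an added SD of 0.5 in 200 of 6000 genes, the mean recovered excess was 0.498. A cell was said to carry a marker list when 3 of its members reached TPM 10, counting members at TPM 1 or more in at most 20% of serum cells. NPC values were compared with serum plates as log2 of plate mean TPM + 1, without a test, as there is 1 NPC preparation in a table of its own.

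ChIP counts were compared as log2 ratios to serum with a pseudocount at the 5th percentile of each mark (7 for H3K4me3, 13 for H3K27ac, 7 for RNA polymerase II, 6 for H3K27me3), without a test, since there is 1 library per condition and antibody and no replicate check. List medians were set beside 10000 random lists matched on serum expression, and, as an addition, 1000 lists matched on the serum count of the mark in 50 bins. The pseudocount shrinks ratios: in simulated windows a true shift of -1.32 was -0.91 with the pseudocount, and -0.76 was recovered relative to random lists. Counting intervals are exact 95% Poisson intervals for counts and exact Clopper-Pearson intervals for shares, and cover counting error only. Sporadic genes were those at TPM 1 or more in 2 to under 50% of cells.

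Named genes follow this rule. In each bulk comparison with serum they are the 10 largest rises and 10 largest falls past the test that moved the same way in every library and in the plate means, without Gm and Rik names and the two-cell-like list. From each list they are up to 4 tested members of largest change. Dgcr8, Pou5f1, Nanog, Esrrb, Klf4, Tfcp2l1, Prdm14, Dnmt3b, Dnmt3l, Lin28a, Myc, Mycn, Cdkn1a, Lats2 and Gata6 are always reported. Of these, Tfcp2l1 is not in the tables under that symbol, and Lats2 and Gata6 lay under the filter in bulk. For variability they are the 10 genes of largest excess in both serum plates, for NPCs the 10 largest differences each way, and for H3K27me3 the 6 largest falls and the 6 values at the other end of the Polycomb-target list. Genes named outside this rule were chosen after their values were seen. For H3K27me3, 1 gene that this rule selects is not reported here.

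Alternatives changed the pseudocount, the filter on low values, the scaling of libraries (each shifted to a median log2 ratio of 0, called centred, or quantile normalised), the trend, single replicates, a replicate block, the correlation of the lists, the average over cells, the detection limit, the measure of variability, the ChIP pseudocount and the input. Other software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.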

Results

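RNA was measured in single mESCs, 183 grown in serum+LIF on a pair of plates (90 and 93 cells), 94 in 2i+LIF and 84 lacking Dgcr8, and in 54 NPCs. Bulk RNA came from 2 serum, 1 2i and 2 knockout libraries. ChIP-seq gave 1 library per mESC condition for each of H3K4me3, H3K27me3, H3K27ac, H3K9me3, H3K36me3, RNA polymerase II and the whole cell extract used as input. At a TPM of at least 1, the bulk libraries held 8365 and 7560 genes in serum, 8989 in 2i and 11054 and 10818 in the knockout. The median cell held 7779 and 7646 genes on the serum plates, 9973 in 2i, 9316 in the knockout and 7351 among NPCs. Counts summed over the 23167 windows were 815042 in serum, 516249 in 2i and 577359 in the knockout for H3K27me3, and 15315269, 9687863 and 5686479 for H3K4me3. They were 4068406, 5124726 and 4173738 for H3K27ac, and 1521860, 902007 and 1632114 for RNA polymerase II. The smaller sums were 502628, 545650 and 333088 for H3K36me3, 408324, 441196 and 369223 for H3K9me3, and 457710, 562581 and 480437 for input.

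Dgcr8 itself was read at 10.6 and 10.3 TPM in the serum bulk libraries, 4.66 in 2i, and 4.03 and 2.20 in the knockout. It fell by 1.51 on the log2 scale in the knockout (SE 0.28, 2 libraries against 2, adjusted p = 3.57e-04, lower in both knockout libraries). In 2i it fell by 1.02 (SE 0.34, adjusted p = 0.0379), a call that 7 alternatives ended. The plate means were 72.5 and 26.99 TPM on the serum plates, 33.95 in 2i and 16.02 in the knockout, where the difference did not pass the test as deposited (adjusted p = 0.243) but did relative to the median gene (-2.79, adjusted p = 0.00128). In the window of Dgcr8, H3K4me3 counts were 1484 in serum, 1030 in 2i and 443 in the knockout (log2 ratio -1.73, against -1.29 for all genes), and RNA polymerase II counts were 210 in serum and 216 in the knockout (log2 ratio 0.04, against 0.11 for all genes), with a log2 ratio of -0.67 in 2i (-0.56 for all genes).

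The comparison of 2i with serum asks how the mESC state differs between 2i+LIF, which blocks ERK signalling and raises Wnt signalling, and serum+LIF. The labels name serum only for the serum+LIF culture, so effects of the inhibitors and of serum cannot be told apart. In 2i, Dnmt3l, a cofactor of the de novo DNA methyltransferases, fell from a mean of 178.1 TPM (SD 26.5, n = 2) to 0.832, and Krt18, a keratin of simple epithelia, from 98.6 (SD 0.64, n = 2) to 0.296. The reproductive homeobox genes Rhox6 and Rhox9 fell (-7.57, SE 0.26, and -6.87, SE 0.25, on the log2 scale), as did Lifr, the LIF receptor (-5.59, SE 0.21). Histone genes Hist2h4 and Hist1h4d rose by 8.16 (SE 0.29) and 5.84 (SE 0.25), and Nupr1, a stress-response gene, rose from 1.56 (SD 1.27, n = 2) to 271 TPM. Among naive pluripotency factors, Esrrb rose by 2.38 (SE 0.29), Prdm14 by 2.05 (SE 0.34), Klf4 by 1.60 (SE 0.31) and Nanog by 1.45 (SE 0.19), and the core factor Pou5f1 rose by 1.01 (SE 0.15, adjusted p = 2.41e-04, or 0.81 relative to the median gene), a call that 1 alternative ended.

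The other large rises in 2i were Xlr3c (5.70, SE 0.37) and Xlr3b (5.29, SE 0.36) of an X-linked family, Aurkc, an Aurora kinase of germ cells (5.29, SE 0.31), and the homeobox gene Crxos1 (5.28, SE 0.45). Crxos1 shares its values with the names Egam1 and Egam-1c, which are counted as separate genes. Xlr3a was listed at 0 in both serum libraries and at 51.9 TPM in 2i. The other large falls were the tight junction gene Cldn6 (-6.50, SE 0.29), the hormone gene Trh (-5.98, SE 0.23), the actin-binding Tmsb4x (-5.03, SE 0.14) and the keratin Krt8 (-4.80, SE 0.27). Sct, which encodes secretin, was at 43.2 and 60.8 TPM in serum and listed at 0 in 2i. Myc was at 9.40 and 8.81 TPM in serum and listed at 0 in 2i, Lin28a fell by 4.67 (SE 0.27), and Mycn did not pass the test (0.75, adjusted p = 0.111). Lats2 stood at 0.234 and 0 TPM in serum and 0.210 in 2i, and Gata6 was listed at 0 in the 5 bulk libraries.

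**Figure D1:**
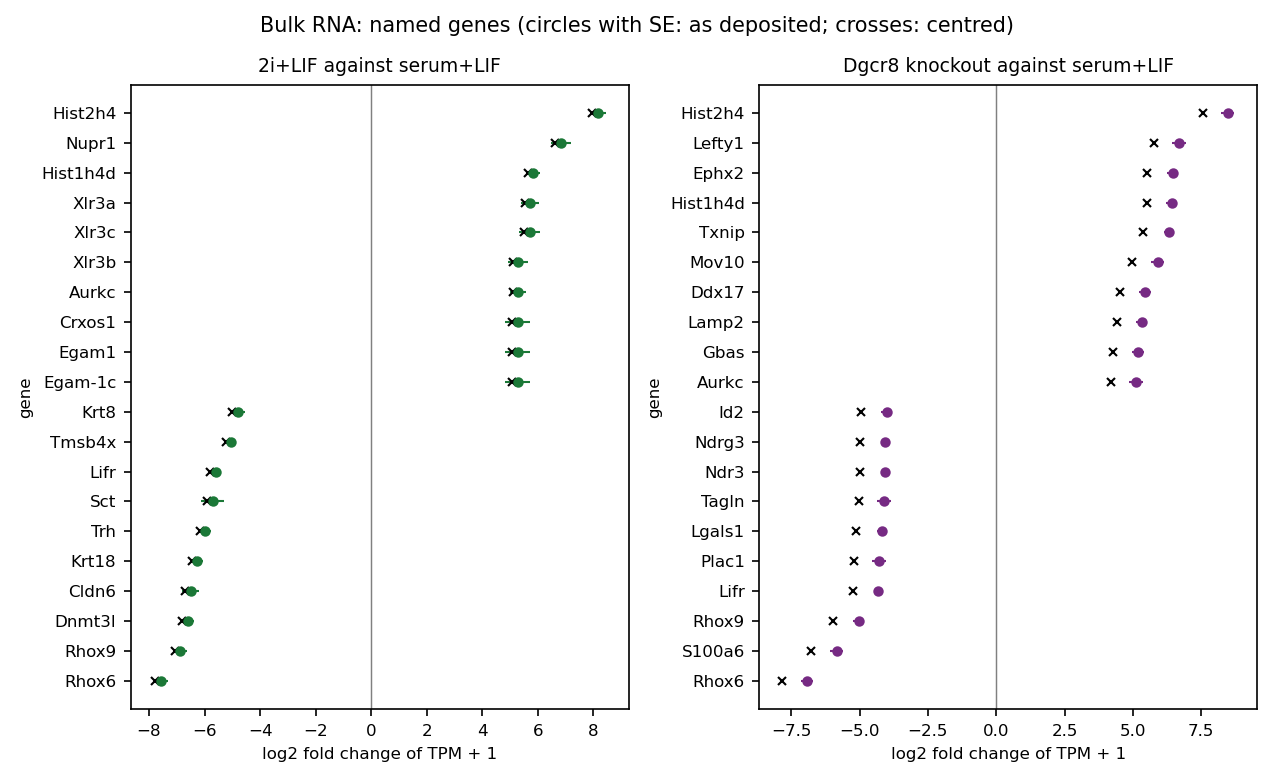
Log2 fold change of TPM + 1 to 2 serum libraries for the named genes in 2i (1 library, left) and the Dgcr8 knockout (2 libraries, right), as deposited (circles, with SE) and relative to the median gene (crosses). Rhox6 lies at -7.57 in 2i and -6.91 in the knockout, and Hist2h4 at 8.16 and 8.47.

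Of 25 tested pluripotency genes, 15 rose, 3 fell and 7 did not pass (adjusted p = 0.00706 for the list, and adjusted p = 0.765 with an estimated correlation). Tcl1, a cofactor of Akt, rose by 3.40 (SE 0.21) and the T-box gene Tbx3 by 2.43 (SE 0.32), while Dppa4 fell by 2.30 (SE 0.20). Primed epiblast genes went the other way: 2 rose, 6 fell and 3 did not pass (2 and 7 adjusted over the list alone; adjusted p = 0.00365, and adjusted p = 0.765 with an estimated correlation). Car4 fell by 3.28 (SE 0.38) and Dnmt3b, a de novo DNA methyltransferase, by 2.72 (SE 0.32), but Zic2 rose by 2.37 (SE 0.29). The primed list shares Krt18 with the trophoblast list, and Dnmt3a and Dnmt3b with the DNA methylation list. Results for these lists are therefore not separate evidence. In the DNA methylation machinery 1 gene rose, 5 fell and 5 did not pass (2 and 5 adjusted over the list alone; adjusted p = 0.00976, and adjusted p = 0.666 with an estimated correlation), among them Dnmt3a (-1.69, SE 0.32) and the glycosylase Tdg (-1.40, SE 0.27). Targets of BMP and Nodal were called lower (1 up, 3 down, 5 not passing; adjusted p = 0.0231, and adjusted p = 0.666 with an estimated correlation), a call that quantile normalisation ended (adjusted p = 0.0697). Its falls were the inhibitors of differentiation Id3 (-4.75, SE 0.28) and Id2 (-3.36, SE 0.25), with Id1, at 19.6 and 14.5 TPM in serum, listed at 0 in 2i.

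Trophoblast genes fell (0 up, 4 down, 1 not passing, and 1 up and 4 down adjusted over the list alone; adjusted p = 6.99e-06, and adjusted p = 0.593 with an estimated correlation). They are Krt7 (-6.32, SE 0.28), Krt8 and Krt18, keratins that other epithelial cells also express, and the placental gene Plac1, listed at 0 in 2i. Imprinted genes were called lower (1 up, 8 down, 4 not passing; adjusted p = 0.00567, and adjusted p = 0.666 with an estimated correlation), with falls of Phlda2 (-3.41, SE 0.36) and the amino acid transporter Slc38a4 (-3.20, SE 0.25) and a rise of Plagl1 (2.51, SE 0.26). Oxidative phosphorylation subunits rose in 62 of 87 cases and fell in 6 (64 and 6 adjusted over the list alone; adjusted p = 1.04e-11, and adjusted p = 0.593 with an estimated correlation), led by Ndufb4 (2.58, SE 0.18) and Cox7a1 (2.47, SE 0.33). Of these 62 rises, 60 were higher in the 2i plate than in both serum plates, but so were 5 of the 6 falls, and the median gene of that plate was 1.24 higher. Enzymes of cholesterol and lipid synthesis rose in 16 of 23 cases with no fall (18 adjusted over the list alone; adjusted p = 8.64e-06, and adjusted p = 0.765 with an estimated correlation), including the sterol sensor Insig1 (3.68, SE 0.35), the desaturase Scd1 (3.02, SE 0.31) and Fdps (2.06, SE 0.15).

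The remaining lists were not called in 2i. Some of their bulk falls were not seen in cells as deposited. In the 2i plate 3 of 3 G2/M falls, 5 of 6 G1/S falls and 3 of 6 glycolysis falls lay above both serum plates. Below both lay 1 G1/S fall and 2 glycolysis falls. All bulk rises of these 3 lists lay above both, in a plate whose median gene was 1.24 higher. ERK targets counted 1 rise and 5 falls among 14 (adjusted p = 0.0867), the falls including the ERK phosphatase Dusp6 (-2.91, SE 0.30) and Ier3 (-1.33, SE 0.42), with Spry4 at 2.40 and 1.69 TPM in serum and listed at 0 in 2i. Germline genes counted 3 rises and 2 falls among 11, with Dazl up by 3.65 (SE 0.35) and Hormad1 by 1.97 (SE 0.36) and Ddx4 down (-1.42, SE 0.31). Glycolysis genes counted 8 rises and 6 falls among 19. There Ldhb rose by 3.92 (SE 0.18), while Ldha, the other lactate dehydrogenase subunit, fell by 1.96 (SE 0.10) and Eno1 by 1.59 (SE 0.10). Rises and falls were 7 and 6 of 23 for G1/S (7 and 7 adjusted over the list alone), with E2f1 up (2.13, SE 0.34) and Mcm5 down (-2.07, SE 0.16), and 6 and 3 of 21 for G2/M (7 and 3), with Hmmr up (1.31, SE 0.22) and Bub1b down (-1.44, SE 0.21). They were 5 and 3 of 16 for p53 targets (7 and 3), where the cell cycle inhibitor Cdkn1a rose by 2.29 (SE 0.27), and 4 and 2 of 16 for Polycomb machinery (6 and 3), where Mtf2 rose by 1.37 (SE 0.24). They were 2 and 2 of 16 for microRNA machinery, 1 and 2 of 7 for miR-290 targets, 5 and 2 of 18 for let-7 targets, 2 and 2 of 14 for stress genes and 1 and 1 of 5 for Myc and partners. Ribosomal protein genes counted 17 rises and 20 falls among 83 (19 and 21 adjusted over the list alone; adjusted p = 0.126), a list called lower after centring (adjusted p = 0.0460). Neither a rise nor a fall passed among 5 two-cell-like genes. Lists with 4 tested genes gave 2 rises for Wnt targets (Tnfrsf19 at 1.48, SE 0.34), 2 rises for neural precursor genes (Sox2 at 2.03, SE 0.27), 2 rises and 1 fall for primitive endoderm (Srgn, listed at 0 in serum, at 3.28 TPM), and 1 rise and 3 falls for fibroblast genes (S100a6 at -4.80, SE 0.28).

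In all, 2053 of 10078 genes rose and 1184 fell in 2i (limma). The median gene was 0.20 higher, and relative to it 1561 rose and 1763 fell, so the share of rises was 63.4% as deposited and 46.96% centred. In the plate means 2349 of 3193 genes called in bulk moved the same way (73.6%, or 84.7% centred). The lone 2i library is assumed to vary like the serum and knockout pairs.

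The knockout comparison sets a Dgcr8 knockout line, which lacks a factor needed for microRNA processing, against v6.5 cells in serum+LIF. Effects of lost microRNA processing and other differences between the lines cannot be told apart. In both knockout libraries Lefty1, a Nodal inhibitor and Nodal target, rose from 0.432 TPM (SD 0.016, n = 2) to 150 (SD 41.5, n = 2), and Txnip, a thioredoxin-binding regulator of glucose uptake, from 20.8 (SD 1.41) to 1720 (SD 44.8). The epoxide hydrolase gene Ephx2 rose by 6.45 on the log2 scale (SE 0.19). Relative to the median gene, which was 0.92 higher in the knockout, these rises were 5.77, 5.38 and 5.53. RNA helicases Mov10 and Ddx17, partners of the Argonaute and Drosha complexes, rose by 5.90 (SE 0.24) and 5.44 (SE 0.23), or 4.98 and 4.52 relative to the median gene. Falls included the calcium-binding S100a6 (-5.83, SE 0.23), Rhox6 (-6.91, SE 0.21) and Lifr (-4.32, SE 0.17), or -6.76, -7.83 and -5.24 relative to the median gene.

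Further rises were Hist2h4 (8.47, SE 0.24, or 7.55 relative to the median gene), Hist1h4d (6.42, SE 0.21, or 5.50), the lysosomal gene Lamp2 (5.32, SE 0.20, or 4.40), Gbas (5.19, SE 0.22, or 4.26) and Aurkc (5.11, SE 0.25, or 4.19). Further falls were Rhox9 (-5.03, SE 0.20, or -5.95), Plac1 (-4.29, SE 0.26, or -5.22), the galectin Lgals1 (-4.19, SE 0.17, or -5.12), Tagln (-4.10, SE 0.25, or -5.03), Ndrg3 (-4.08, SE 0.14; the name Ndr3 carries the same values) and Id2 (-4.01, SE 0.21, or -4.93). Cdkn1a, a known target of the miR-290 family, rose from 1.32 and 1.38 TPM to 57.5 and 56.5. Pou5f1 rose by 1.60 (SE 0.12), Nanog by 1.37 (SE 0.16), Esrrb by 1.92 (SE 0.24) and Prdm14 by 2.97 (SE 0.28), or 0.68, 0.45, 0.99 and 2.05 relative to the median gene. Klf4 rose by 0.84 (SE 0.25, adjusted p = 0.00909) as deposited, but stood at -0.08 relative to the median gene (adjusted p = 0.751). Dnmt3l (-3.07, SE 0.20), Lin28a (-3.38, SE 0.22), Myc (-2.77, SE 0.27) and Dnmt3b (-1.99, SE 0.26) fell on both scales, and Mycn fell by 0.69 (SE 0.28, adjusted p = 0.0383), a call that 4 alternatives ended and that the plates do not show (27.5 and 18.6 TPM in serum, 26.9 in the knockout). Nanog moved the other way in the plates, where its means were 820 and 1710 TPM in serum, 918 in 2i and 368 in the knockout, a difference that did not pass as deposited (adjusted p = 0.132) and did relative to the median gene (-3.06, adjusted p = 0.00417).

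**Figure D2:**
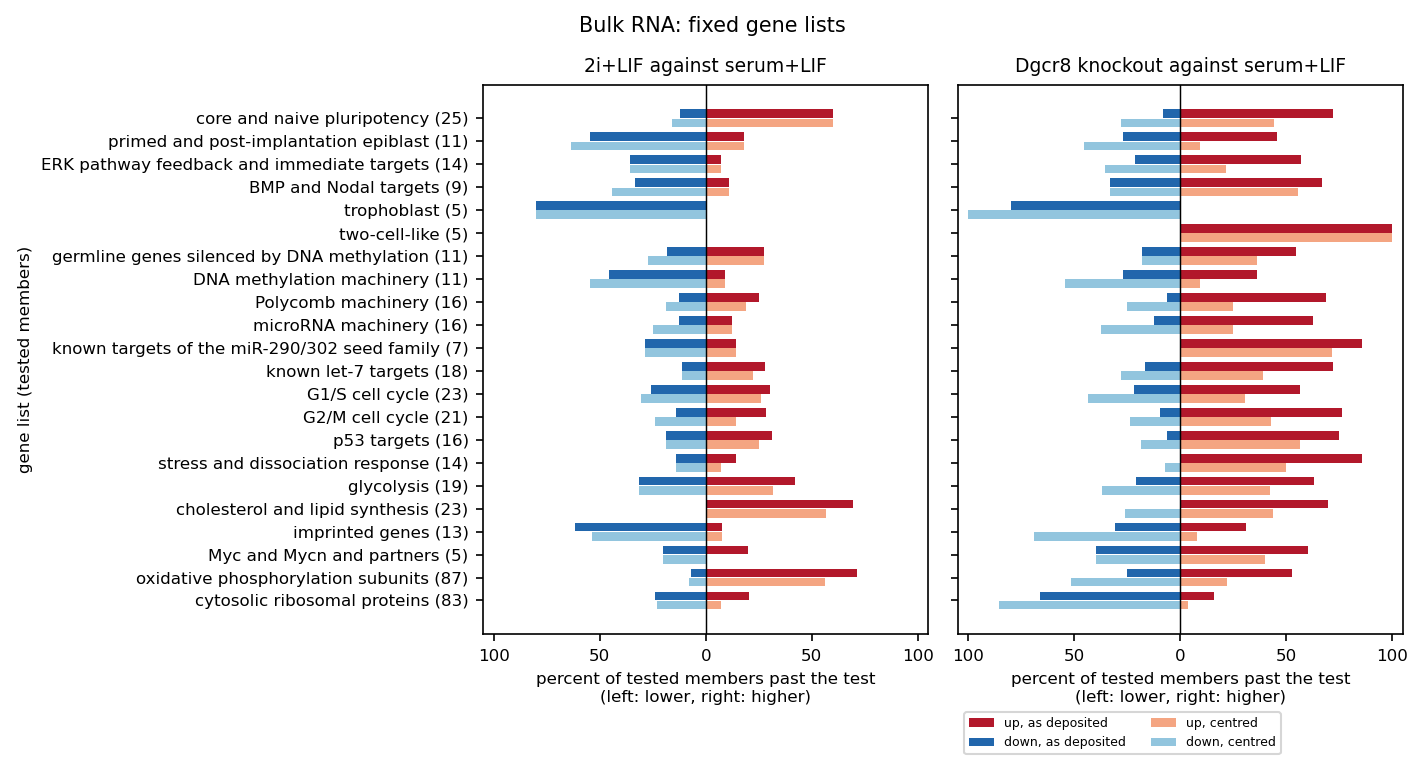
Percent of tested members of each gene list that rose (right) or fell (left) in bulk RNA in 2i and in the Dgcr8 knockout against serum, as deposited (dark) and relative to the median gene (light). Oxidative phosphorylation in the knockout counts 46 rises and 22 falls of 87 as deposited and 19 and 45 relative to the median gene.

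Ribosomal protein genes were called lower in the knockout bulk libraries: 13 rose, 55 fell and 15 of 83 did not pass (3 and 71 relative to the median gene; adjusted p = 3.87e-30, and adjusted p = 0.268 with an estimated correlation). Rps27l fell by 3.45 (SE 0.11) and Rpl35a by 2.80 (SE 0.10), whereas Rps2 rose by 4.21 (SE 0.23). The single cells differed as deposited: of the 55 genes, 19 were lower in the knockout plate than in both serum plates and 15 were higher than in both. The list had a median change of 0.03 in that plate, whose median gene was 1.38 higher. Relative to the median gene the list was therefore lower in the cells too. For Rps27l the plate means were 930 and 1079 TPM in serum and 932 in the knockout. Oxidative phosphorylation subunits counted 46 rises and 22 falls among 87 as deposited and 19 and 45 relative to the median gene, but 40 and 26 with quantile normalisation. The list test, which weighs a list against other genes, pointed down as deposited and centred and was called only centred (adjusted p = 0.0726, 0.0234, and 0.150 with quantile normalisation). Atp5b rose by 4.17 (SE 0.12) and Cox6b2 by 4.38 (SE 0.20), and Atp5e fell by 3.15 (SE 0.17). Of those 22 falls, 1 was below both serum plates in the knockout plate and 16 were above both, and of the 46 rises 45 were above both, in a plate whose median gene was 1.38 higher. Whether the knockout and serum bulk libraries were prepared alike is not given in the sources used here, so a technical source of these falls in bulk is not excluded.

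Known targets of the miR-290 family rose in 6 of 7 cases with no fall (5 relative to the median gene), with Ei24 at 3.20 (SE 0.24), Casp2 at 2.40 (SE 0.25) and Rbl2 at 1.94 (SE 0.24), or 2.28, 1.48 and 1.02 relative to the median gene. The list was not called (adjusted p = 0.117, 0.0477 centred, 0.0621 with quantile normalisation, and adjusted p = 0.773 with an estimated correlation), and its 6 rises were above both serum plates in the cells, where the median gene was also higher. Trophoblast genes were called lower (0 up, 4 down, 1 not passing; adjusted p = 1.47e-04, and adjusted p = 0.518 with an estimated correlation), with Krt7 at -3.64 (SE 0.23). In the knockout plate 2 of the 4 falls were below both serum plates, and Krt7 was not (3.88 TPM against 0.772 and 10.2). Krt18 did not pass (-0.02, adjusted p = 0.945), though it lay at -0.94 relative to the median gene (adjusted p = 0.00120). Imprinted genes were called lower with 4 rises and 4 falls among 13 (1 and 9 centred; adjusted p = 0.0370, and adjusted p = 0.773 with an estimated correlation), including Peg10 (-1.52, SE 0.25) and the rise of Ndn (2.19, SE 0.25).

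The other lists were not called in the knockout as deposited. The 5 two-cell-like genes rose (Zscan4f by 3.80, SE 0.28, and Zscan4c by 3.46, SE 0.25). The list test (camera) gave adjusted p = 0.0726, or 0.0142 centred and 0.0194 with the replicate block. These Zscan4 genes were listed at 0 in every mESC plate, while Gm4340 (3.68 in bulk, SE 0.30) was at TPM 1 or more in 7.14% of knockout cells and at 0 on the other mESC plates. Stress genes rose in 12 of 14 cases with no fall (7 and 1 centred; adjusted p = 0.0726), with Fos, from 1.95 and 1.84 TPM to 35.7 and 32.4, and Egr1 at 2.78 (SE 0.26), which are also ERK targets, a list of 8 rises and 3 falls among 14 (3 and 5 centred). Pluripotency genes counted 18 rises and 2 falls among 25 (11 and 7 centred), with Sox2 at 4.22 (SE 0.22, or 3.29 relative to the median gene) and Utf1 at 2.82 (SE 0.34, or 1.90). Primed genes counted 5 rises and 3 falls of 11 (1 and 5 centred, with the list test pointing down on both scales), with Otx2 at 2.41 (SE 0.25). BMP and Nodal targets split between rises of Lefty1 and Lefty2 (3.91, SE 0.26) and falls of Id2 and Id3 (-3.80, SE 0.23), 6 and 3 of 9.

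Targets of p53 counted 12 rises and 1 fall of 16 (9 and 3 centred), with Ccng1 at 3.49 (SE 0.25) and Pmaip1 at 3.10 (SE 0.24). G2/M genes counted 16 and 2 of 21 (9 and 5 centred), with Nusap1 at 3.62 (SE 0.20), and G1/S genes 13 and 5 of 23 (7 and 10 centred), with Mcm5 at -1.99 (SE 0.13). Known let-7 targets counted 13 and 3 of 18 (7 and 5 centred), with Igf2bp2 at 2.96 (SE 0.24). The counts were 12 and 4 of 19 for glycolysis (8 and 7 centred; Aldoc at 4.09, SE 0.24), 16 and 0 of 23 for cholesterol and lipid synthesis (10 and 6 centred; Mvd at 2.72, SE 0.25) and 6 and 2 of 11 for germline genes (7 and 2 adjusted over the list alone; Hormad1 at 2.80, SE 0.29). They were 11 and 1 of 16 for Polycomb machinery (4 and 4 centred; Ezh1 at 3.17, SE 0.28), 10 and 2 of 16 for microRNA machinery (4 and 6 centred), 4 and 3 of 11 for DNA methylation machinery (1 and 6 centred) and 3 and 2 of 5 for Myc and partners. Among 4 tested genes each, Wnt targets gave 3 rises (Ccnd1 at 2.45, SE 0.26), primitive endoderm 2 (with Srgn, listed at 0 in serum and at 11.6 TPM in knockout replicate 1), neural precursor genes 2 (Vim at 3.41, SE 0.26), and fibroblast genes 3 falls (Acta2 at -2.79, SE 0.25).

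In total 6303 of 10078 genes rose and 1183 fell, with 84.2% of calls up as deposited and 48.5% relative to the median gene (2857 and 3038). In the plates 6743 of the 7359 genes called in bulk moved the same way (91.6%, or 88.3% centred). The 20 highest genes held 40.1% and 38.2% of TPM in the knockout libraries, against 30.7% and 31.6% in serum and 32.04% in 2i.

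Setting 2i directly against the knockout, which removes the shared serum libraries, gave Utf1 at -4.78 (SE 0.41), Krt18 at -6.25 (SE 0.22), Lefty1 at -5.46 (SE 0.31) and Gm4340 at -4.12 (SE 0.36), all lower in 2i, and Klf5 at 1.75 (SE 0.38) and Dazl at 2.05 (SE 0.35), both higher in 2i. Relative to the median gene, which was 0.72 lower in 2i (-0.72), these were -4.05, -5.52, -4.73, -3.40, 2.48 and 2.78. All 7 targets of the miR-290 family were lower in 2i (Rhoc at -3.65, SE 0.30; adjusted p = 0.0226, and adjusted p = 0.572 with an estimated correlation), as were the 5 two-cell-like genes (the same adjusted p values) and 13 of 14 stress genes (5 relative to the median gene; adjusted p = 0.0433, 0.0510 centred, and adjusted p = 0.711 with an estimated correlation). Lists called higher in 2i were ribosomal protein genes (52 up and 13 down of 83, or 54 and 14 adjusted over the list alone and 67 and 4 centred; adjusted p = 2.01e-24, and adjusted p = 0.331 with an estimated correlation), oxidative phosphorylation (42 and 21 of 87, or 56 and 11 centred; adjusted p = 4.53e-12, and adjusted p = 0.572 with an estimated correlation) and cholesterol and lipid synthesis (7 and 5 of 23, or 16 and 1 centred; adjusted p = 0.0367, and adjusted p = 0.890 with an estimated correlation). Rps27l stood at 3.74 (SE 0.14), Cox7b at 4.42 (SE 0.19) and Uqcrq at 4.02 (SE 0.17), while Scd1 was higher by 1.85 (SE 0.31). The ribosomal difference was not seen in cells, where the list had median log2 changes to serum of -0.08 in 2i and 0.03 in the knockout, against 1.505 and 1.28 for oxidative phosphorylation. The doubt about how the knockout bulk libraries were prepared applies here too. Counting each set of identical values once left 3 of these 6 lists called. In all, 1198 genes were higher and 4951 lower in 2i, or 2639 and 2438 relative to the median gene.

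The changes of 2i and knockout were set against each other, with the serum libraries in common. Across 10078 genes (which are not independent replicates) the bulk fold changes of 2i and knockout correlated at 0.427, where unchanged groups against the same serum libraries gave 0.407 (range 0.372 to 0.428). It lay above the simulated range with a pseudocount of 0.1 (0.462 against 0.354 to 0.438) and for genes of mean TPM at least 5 (0.454 against 0.369 to 0.437). The covariance was 0.4997 against 0.031 in the simulations, a difference of 0.468. With separate serum plates as controls the correlation of plate means was 0.650 (simulated -0.043 to 0.052). Yet both serum plates differed alike from the others, with 7779 and 7646 genes in the median cell against 9973 in 2i and 9316 in the knockout. The simulations hold no difference common to both serum plates. This correlation therefore does not by itself show shared change either. Relative to the median gene, 781 genes rose in both (443 by the product of the margins over all genes) and 1071 fell in both (531), while 244 rose in 2i and fell in the knockout (471) and 205 did the opposite (500). This product leaves out the serum libraries in common, so the overlaps do not by themselves show shared change. After centring, 61.7% of genes had the same sign in both bulk comparisons, against 63.4% in the simulations. Those simulations held no change, so their share is no baseline for overlaps of called genes. With separate serum plates as controls, 70.97% of genes had the same sign after centring, against 49.96% in the simulations. The limit given for the correlation of plate means applies to this share too. Rhox6, Rhox9, Lifr, Lin28a and Dnmt3l fell in both and Hist2h4, Hist1h4d and Aurkc rose in both.

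In the plates Esrrb went from 4.65 and 3.46 TPM on the serum plates to 48.98 in 2i and 30.8 in the knockout, Prdm14 from 0.629 and 0.754 to 12.04 and 12.8, and Cdkn1a from 3.91 and 3.17 to 61.1 and 112.9. Pou5f1 went from 57.5 and 39.5 to 145.6 and 146.5, Klf4 from 4.13 and 4.61 to 44.8 and 24.1, and Lats2 from 0.392 and 0.247 to 1.501 and 2.51. Mycn stood at 27.5 and 18.6 in serum, 24.98 in 2i and 26.9 in the knockout. Lower were Dnmt3l (93.1 and 92.1 in serum, 2.60 in 2i and 25.9 in the knockout), Lin28a (28.7 and 27.3, 3.82 and 6.17), Dnmt3b (23.9 and 17.9, 8.07 and 10.8) and Myc (13.8 and 11.7, 0 and 0.862), and Gata6 was listed at 0. In 2i 4830 of 12394 genes rose and 226 fell, and in the knockout 6199 rose and 368 fell (limma, 1 residual degree of freedom). The median gene was 1.24 and 1.38 higher, and relative to it the counts were 1923 and 2296 in 2i and 2765 and 2808 in the knockout. Leaving out the 200 highest genes and rescaling lowered the numbers of calls to 1846 and 3090.

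Targets of BMP signalling differed between cells in serum. The BMP target Id1 had an SD over cells of 2.77 and 2.34 log2 units on the serum plates, and averaged 63.9 TPM on plate 2 against 1.47 in 2i. BMP and Nodal targets had a median excess SD of 0.340 and 0.692 over genes of like level on the serum plates, above 99.7% and 100% of matched random lists, 0.373 in the knockout (99.8%) and 0.068 in 2i (77.9%). These medians rest on 7 and 6 genes on the serum plates, 12 in the knockout and 11 in 2i, so the members differ. By coefficient of variation BMP and Nodal targets were above most matched lists in 2i too (0.429, 99.27%). Trophoblast genes had an excess of 0.516 and 0.711 on the serum plates (100% each), 0.010 in 2i and -0.003 in the knockout, over 5, 6, 7 and 7 genes. By coefficient of variation they were also above most matched lists in 2i (0.650, 99.38%) and in the knockout (0.328, 94.8%), though less far than on the serum plates (1.40 and 3.12, both 100%). Krt18 reached TPM 1 in 58.9% and 59.1% of serum cells, 21.3% of 2i cells and 96.4% of knockout cells.

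Germline genes varied beyond matched lists on all mESC plates, with excesses of 0.248, 0.366, 0.393 and 0.261 for the serum plates, 2i and the knockout. Dazl reached TPM 1 in 18.3% of the cells of serum plate 2, 88.3% of 2i cells and 40.5% of knockout cells. Stress genes were also above most matched lists (0.221, 0.228, 0.281 and 0.157), while p53 targets differed between the serum plates (0.307 and 0.050). Pluripotency genes had excesses of 0.103 and 0.072 in serum, -0.008 in 2i and 0.000 in the knockout, so the list lay above 94.99% and 88.1% of matched lists in serum, but by coefficient of variation above 54.9% and 44.7%. Nanog had an SD of 0.997 and 0.796 in serum, 0.514 in 2i and 0.758 in the knockout, and Dppa3, a maternal factor of early embryos, an excess of 1.45, 1.41, 0.731 and 1.66. Ribosomal protein genes varied less than any of the 10000 matched lists on each mESC plate (-0.104, -0.079, -0.043 and -0.076). MicroRNA machinery (-0.124, -0.158, -0.316 and -0.328) and let-7 targets (-0.078, -0.088, -0.215 and -0.318) also varied less than most matched lists on each mESC plate. The 10 genes of largest excess in both serum plates were AB352479 (2.58 and 2.82), Hist1h2ah (2.09 and 1.98), Rhox6 (1.96 and 2.14), Rn4.5s (1.90 and 2.23), Hist1h2an (1.93 and 1.84), Hist1h2af (2.09 and 1.78), M13188 (1.78 and 2.15), Rhox9 (1.77 and 2.11), Hist1h2ai (2.07 and 1.75) and Gstp2 (1.74 and 1.61).

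**Figure D3:**
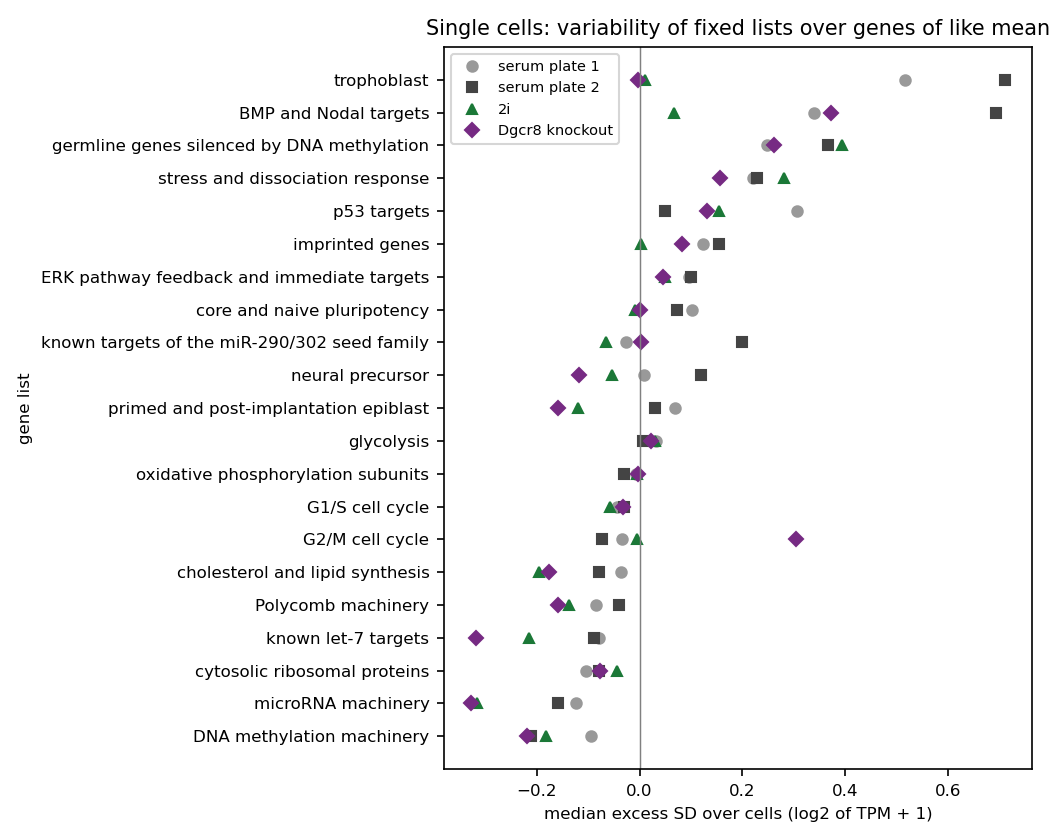
Median excess SD over cells (log2 of TPM + 1, relative to genes of like mean level) of each gene list on the 4 mESC plates. Only members with a plate mean TPM of at least 1 enter, so members can differ between plates. Trophoblast genes lie at 0.516 and 0.711 on the serum plates and at 0.010 in 2i.

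Over 3317 genes with a plate mean of at least 10 TPM on each mESC plate, the median SD was 0.892 and 0.807 in serum, 0.698 in 2i and 1.12 in the knockout. The knockout value lay above serum by more than the difference of 0.085 between the serum plates, but its coefficient of variation, 0.636, lay between those of the serum plates, 0.667 and 0.576. Among 191 genes with like means on the 4 plates the SD was 0.675 and 0.604 in serum, 0.607 in 2i and 0.852 in the knockout. Their coefficient of variation was 0.493 and 0.431 in serum, 0.392 in 2i and 0.533 in the knockout, so there the knockout lay above both serum plates. Sporadic genes made up 40.5% and 41.97% of genes on the serum plates, 30.7% in 2i and 38.4% in the knockout, but at a limit of TPM 10 the order turned (45.7%, 36.8%, 48.05% and 56.003%). Conditions other than serum have 1 plate each, so no test was made.

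Genes of some lists rose and fell together across cells. G2/M genes had a mean pairwise Spearman correlation of 0.277 and 0.230 in serum, 0.462 in the knockout and 0.476 in NPCs, above all 1000 matched lists on these plates. Pluripotency genes gave 0.103 and 0.115 in serum, 0.051 in 2i and 0.048 in the knockout, where random lists had medians of 0.048, 0.030, 0.006 and 0.017, so they lay above 93%, 99.8%, 100% and 98.7% of them. Neural precursor genes did not vary together in serum (-0.036 and -0.035). Targets of p53 gave 0.232, 0.208, 0.112 and 0.077. Of the marker lists, primitive endoderm was carried by 2 of 84 knockout cells (2.38%, exact 95% interval 0.290 to 8.34), and no other mESC carried a list of primitive endoderm, trophoblast, mesoderm, two-cell-like, neural or fibroblast markers. The counts of 0 allow shares of up to 4.02% and 3.89% on the serum plates, 3.85% in 2i and 4.30% in the knockout (exact 95% intervals). Among NPCs, 47 of 54 carried the neural list (87.04%, interval 75.1 to 94.6), 40 the fibroblast list (74.1%, interval 60.3 to 85.04) and 17 the primitive endoderm list (31.5%, interval 19.5 to 45.6).

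NPCs were set beside serum mESCs to show what a differentiated state looks like in the same assay. Lens crystallin genes led: Cryaa averaged 7078 TPM in NPCs against 0.048 and 7.01 on the serum plates, Cryab 2963 against 2.11 and 3.48, and Cryba1 683 against 0 and 0.912. The secretion factor Wls, Anxa1, Fstl1, the immediate early genes Fos and Egr1, and the basement membrane collagen Col4a1 were higher by 8.16, 7.94, 7.92, 8.07, 7.86 and 7.76 log2 units, and the transcription factor Maf averaged 221 TPM and was listed at 0 in serum. Lower in NPCs were Lepr (-6.45), Hlcs (-6.33), Pla2g1b (-6.28), Arhgef4 (-6.01), Padi4 (-5.88), Cyp2e1 (-5.85), Ptcra (-5.84), Phkg1 (-5.80), Cxcr2 (-5.76) and Qsox1 (-5.72). Several of these stood at high levels on the serum plates (Hlcs at 5811 and 4065 TPM, Cxcr2 at 5481 and 4431), and Ptcra and Cyp2e1 belong to a set of transcripts higher on the serum plates than on the 2i and knockout plates, whose source is open. A technical source of these serum levels is not excluded. The NPC table was normalised apart from the mESC table, its median gene was 1.65 higher (0.325 with a mean of logs over cells), and there is no replicate.

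Neural precursor genes were at least 2-fold higher than on both serum plates in 13 of 15 cases (median 4.43, matched random lists 1.71), fibroblast genes in 13 of 15 (4.83, random 1.35), primitive endoderm genes, which include basement membrane genes, in 10 of 10 (4.58, random 1.49) and miR-290 targets in 14 of 14 (3.35, random 1.94). With a mean of logs over cells the list medians were 3.21, 2.20, 1.77 and 1.58, each above at least 99.87% of matched lists. Also above most matched lists were p53 targets (15 of 16), imprinted genes (18 of 22), stress genes (13 of 18), cholesterol and lipid synthesis (21 of 24) and Polycomb-target regulators (11 of 13). Of all 14312 genes compared, 9219 were at least 2-fold higher than both serum plates and 1027 at least 2-fold lower. Lower by at least 2-fold than both plates were 10 of 24 pluripotency genes (6 were higher; median -0.58, or -3.14 with a mean of logs) and 3 of 10 germline genes (-0.94, or -1.08), each below nearly all matched lists. So were 4 of 6 trophoblast genes (median -2.69), a list whose place depends on the averaging (-0.73 and percentile 8.68 with a mean of logs). Ribosomal protein genes had a median of -0.58, with 8 of 83 lower and none higher by 2-fold.

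The ChIP libraries ask how chromatin marks differ between the mESC conditions. H3K27me3 is the mark laid down by Polycomb complex PRC2. Its log2 ratio to serum was lower at each of the 41 Polycomb-target regulators than at the median gene, in 2i and in the knockout. Their median log2 ratio to serum was -1.45 in 2i and -1.21 in the knockout, against all-gene medians of -0.31 and -0.21. Their median counts, 56 and 66 reads, still lay above those of the median window (16 in 2i and 18 in the knockout). Genes with like H3K27me3 in serum dropped nearly as far: random lists matched on it had medians of -1.24 and -1.02, and the list lay at percentiles 0.1 and 0.15 of them. With 1 library per condition, a weaker immunoprecipitation and a lower mark cannot be told apart.

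**Figure D4:**
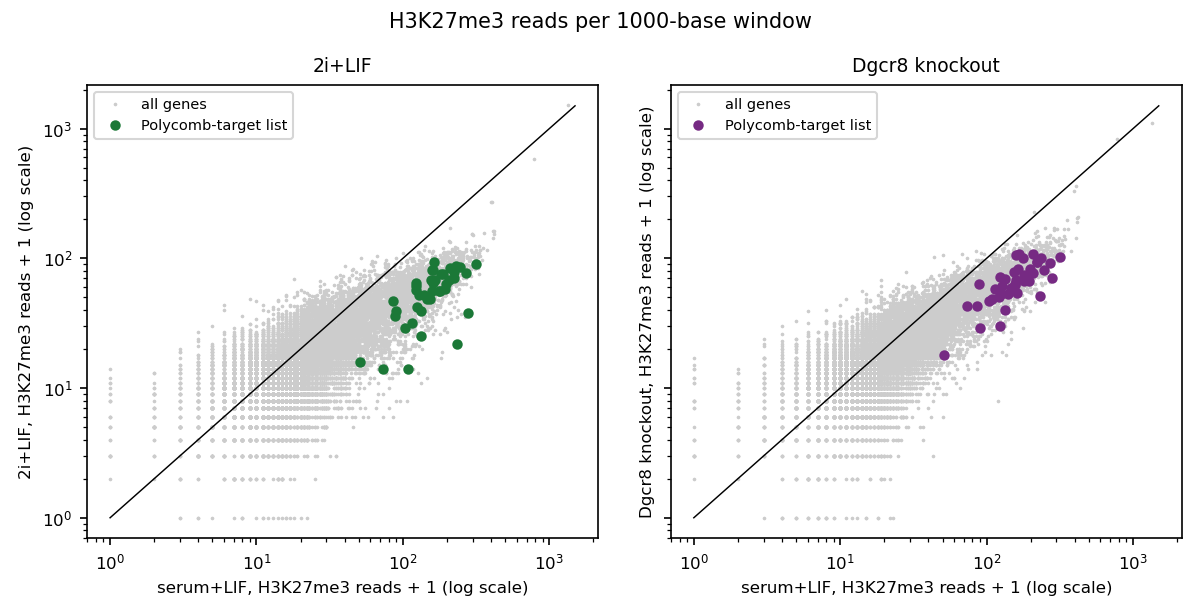
H3K27me3 reads + 1 per 1000-base window in 2i (left) and the Dgcr8 knockout (right) against serum, on log axes with the line of equal counts, for all genes (grey) and 41 Polycomb-target genes (colour), 1 library each. The Polycomb-target medians are 56 in 2i and 66 in the knockout, and other genes of like serum count also lie below the line.

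Among the largest drops in 2i were those at the mesendoderm gene Gsc (chromosome 12, 105710946 to 105711946, mm9), with 233 reads in serum and 21 in 2i (log2 ratio -3.15), Hoxd9 (chromosome 2, 74535319 to 74536319; -2.72), En2 (chromosome 5, 28491735 to 28492735; -2.58), Hoxc5 (-2.21), Gata3 (-2.04) and Neurog1 (-1.76). Among the smallest were those at Irx3 (-0.78), Neurod1 (-0.81), Wnt6 (-0.87), Gata6 (-0.92) and Dlx2 (-0.94). In the knockout large drops were at Msx1 (chromosome 5, 38215324 to 38216324; -2.07), Hoxd9 (-1.92), Lhx2 (-1.62), Neurog1 (-1.58) and Gata4 (-1.52), and small ones at Runx1 (-0.45), Dlx2 (-0.56), Tbx2 (-0.58), Gata3 (-0.70), Wnt6 (-0.73) and Sox7 (-0.79). Mesoderm genes had medians of -1.36 in 2i, near the matched -1.29, and of -1.24 in the knockout. BMP and Nodal genes in the knockout lay further down than genes of like mark (-1.30 against -0.57, counts 52 and 15), as did Wnt targets (-1.12 against -0.76) and neural precursor genes (-1.05 against -0.71).

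Active marks at several lists differed from those at other genes, whether or not the list was called in bulk RNA. At ERK targets in 2i, H3K4me3 went from a median of 1240 to 456 reads, RNA polymerase II to 42 (log2 ratio -1.56) and H3K27ac from 406 to 222, each below the all-gene median in 19 of 19 genes. Primed genes had less H3K4me3 (-1.69) and RNA polymerase II (57 and 14) in 2i. Pluripotency genes had more H3K27ac in 2i (240.5 and 485 reads; 0.59 against 0.22 for all genes) and in the knockout (281.5 reads; 0.37 against -0.12), with more RNA polymerase II in the knockout (0.73 against 0.11). The two-cell-like list had higher counts of H3K27ac (22 and 43 reads) and RNA polymerase II (14 and 28) in the knockout. These were low: the median window held 81 and 63 reads of H3K27ac and 27 and 32 of RNA polymerase II in serum and knockout. Input held 19 in each. The counts do not by themselves show a gain at this list. At Lin28a, H3K4me3 counts were 1154 in serum, 40 in 2i and 140 in the knockout, and at Dnmt3l 334 in serum and 31 in 2i. In 2i Prdm14 had more H3K27ac (log2 ratio 2.18) and less H3K27me3 (-2.46), and Nanog more H3K27ac (1.45). Across 8688 genes, which are not independent replicates, log2 ratios to serum of mark and bulk RNA correlated at 0.404 for H3K4me3, 0.407 for H3K27ac, 0.280 for RNA polymerase II and -0.101 for H3K27me3 in 2i, and at 0.198, 0.192, 0.232 and -0.042 in the knockout. Input gave 0.034 and 0.024.

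Chromatin was also set beside the share of cells that express a gene. In serum the median H3K27me3 count was 32 for genes seen in under 2% of cells, 19 for sporadic genes, 15 for those in 50 to under 95% and 14 for those in at least 95%, while H3K4me3 rose through the same classes in its medians (58, 688.5, 1095 and 1521). In 2i the H3K27me3 medians were 27, 19, 14 and 12, and in the knockout 28, 21, 15 and 13. Sporadic genes with high H3K4me3 were detected in 24.6% of serum cells against 20.3% for those with low H3K4me3 at like mean expression (median difference 3.11 points, higher in 20 of 20 bins), and by 7.45 points more in 2i and 7.44 in the knockout. With H3K27me3 the difference was -1.74 points, and with input 1.07. At a detection limit of TPM 10 the H3K4me3 difference turned to -1.06 points in serum and in 2i and shrank to 0.298 in the knockout.

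**Figure D5:**
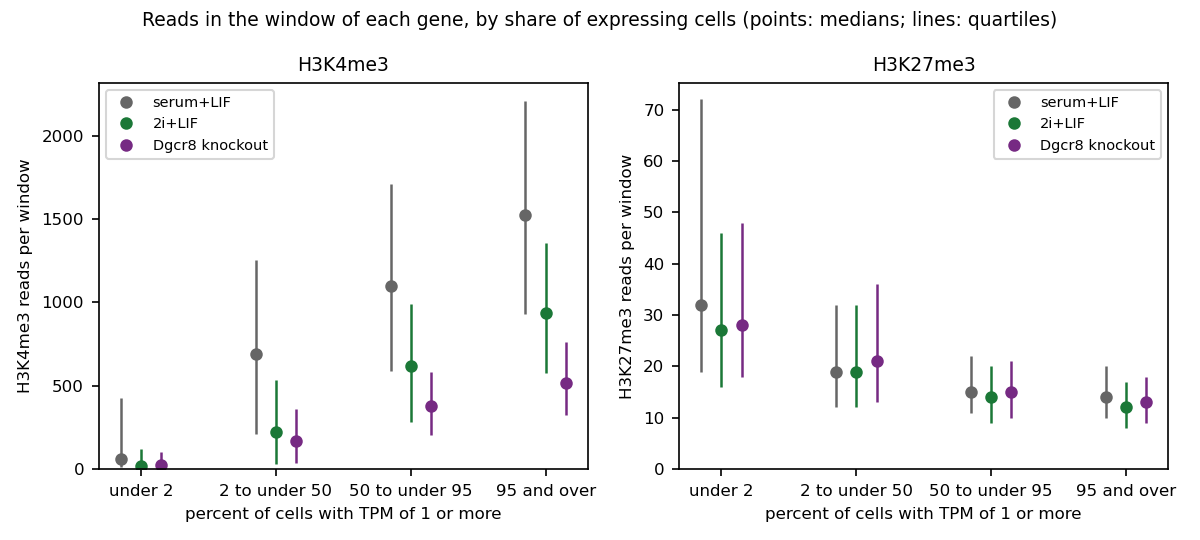
H3K4me3 (left) and H3K27me3 (right) reads per window, as medians with quartiles, for genes grouped by the percentage of cells at TPM 1 or more in serum, 2i and the Dgcr8 knockout. H3K27me3 in serum goes from 32 in the lowest class to 14 in the highest, and H3K4me3 from 58 to 1521.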

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

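The alternatives that counted identical values once, left out the 200 highest genes or matched random lists on the mark were chosen after the results were seen; the others were planned. Of 805 values of single genes under alternatives, 789 kept their direction and side of the threshold, 14 kept the direction but lost the call and 2 reversed. Of the summary values, 72 stayed within their limits, 32 moved and 4 reversed. The lost calls were Dgcr8 in 2i (7 settings), Mycn (4) and Klf4 (2) in the knockout, and Pou5f1 in 2i (1). Read depth of the RNA libraries is not in TPM and limits what low values show; the cell filter removed 0 cells and gave no value. Where a cause is not named, the cause was not tested.

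Without a filter on low values, 1515 genes were called in 2i against serum (main count 3237), with more genes tested. Genes of mean TPM at least 5 gave 4274 in the knockout (7486) and 3822 for 2i against the knockout (6149), with fewer genes tested. Leaving out 1 replicate, with a lone library assumed to vary like the others, gave 2072 to 2689, 5682 to 7530 and 4219 to 6396. The lowest 2i count came without knockout replicate 2, with fewer samples for the spread. The replicate block called 7831 genes in the knockout (6595 up, 1236 down), but differences between replicates correlated at -0.025 across the serum and knockout pairs, so the numbers share only a label. In the plates, the mean of logs over cells gave 7597 genes in 2i, and without the 200 highest genes the counts were 1846 in 2i and 3090 in the knockout.

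With an estimated correlation 0 lists were called in each comparison (main numbers 8, 3 and 6). In 2i the trophoblast and the BMP and Nodal lists lost their calls. Their estimated correlations were -0.217 and -0.106, under the preset of 0.01. For these lists a higher correlation between genes therefore does not account for the loss. The bulk fit has 2 residual degrees of freedom, and whether these limit that version of the test was not examined. Centring gave 6 lists in the knockout. With identical values counted once, 2 were called in the knockout and 3 for 2i against the knockout. Without serum replicate 2, 6 were called in 2i and 2 in the knockout, and without knockout replicate 1, 4 for 2i against the knockout. Klf4 in the knockout reversed to -0.0785 centred and -0.248 with quantile normalisation. The correlation of shared changes was 0.462 with a pseudocount of 0.1, 0.454 at TPM 5 and 0.650 with separate serum plates.

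At a detection limit of TPM 10, the difference to serum in the share of sporadic genes reversed to 6.76 points in 2i (main -10.5) and 14.7 in the knockout (-2.84), the sporadic H3K27me3 medians were 16, 15 and 17 in serum, 2i and knockout, and the matched H3K4me3 differences were -1.06, -1.06 and 0.298. Serum plate 1 alone gave 20 and 4.44 for these. The knockout excess in median SD was 0.354 with a pseudocount of 0.1 and 0.0145 as coefficient of variation (main 0.273). Removing the effect of detected genes gave a pluripotency co-variation of 0.335 in NPCs, and the mean of logs an NPC median of 0.325. H3K27me3 at Polycomb targets was -1.14 centred, -1.38 with the pseudocount at the 25th percentile, -1.77 over input and -0.22 relative to lists matched on the mark in 2i, and -0.996 centred, -1.32 over input and -0.19 relative to matched lists in the knockout.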

Other observations

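The test of the 200 highest genes, the test of highly expressed genes and both tests of NPC transcripts were chosen after the result was seen. NPCs also differed from mESCs in how their own cells varied. G2/M genes had an excess SD of 0.527 and oxidative phosphorylation subunits of 0.425 in NPCs, each above 100% of matched lists, against -0.034 and -0.073 for G2/M on the serum plates and 0.305 in the knockout (above 99.4%). These rest on the SD: by coefficient of variation oxidative phosphorylation was at -0.119 in NPCs (percentile 0.955) and G2/M at 0.086 (percentile 79.3), with G2/M in the knockout at percentile 61.5. Pairwise correlations between cells had a median of 0.564 in NPCs, 0.785 in the knockout, 0.870 in 2i, and 0.886 and 0.901 in serum.

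Marks at other gene groups were also compared. Germline genes had like H3K4me3 medians in serum and 2i (58 and 55 reads, 0.33 against -0.60 for all genes) and in the knockout (54 reads, -0.41 against -1.29). These counts were low, as the median window held 273 reads in serum. The 5th percentile of windows did not drop (4 in serum, 5 in 2i and 6 in the knockout). The ratios therefore do not by themselves set this list apart from other genes of low H3K4me3. At the DNA methylation machinery, median H3K27me3 counts were 15 in serum and 21 in 2i (0.52 against -0.31). Input medians over all windows were 19 in serum and 23 in 2i. These H3K27me3 counts lay near that level and do not by themselves show a gain of the mark. Imprinted genes had less H3K27ac in 2i (81 and 66 reads) and in the knockout (44 reads). Trophoblast genes had less H3K4me3 in 2i (213.5 and 69 reads), and enzymes of cholesterol and lipid synthesis kept more RNA polymerase II there than other genes (-0.32 against -0.56).

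Most genes were read at higher TPM in the knockout bulk libraries than in serum. Without the 200 highest genes the smallest of the 4 library pairs still differed by 0.737 log2 (12894 genes), which argues against a few genes taking most of the counts as the whole cause. Genes of TPM 100 or more differed by -0.244, while genes of 20 to 100 TPM differed by 0.707, those of 5 to 20 by 1.13 and those of 1 to 5 by 0.9751. The value of the highest genes met the bound set for a depth difference, but a fixed total forces the highest genes down when most others rise, so depth and a true rise cannot be told apart by it. Loss of microRNAs, which lower many messages, may contribute and was not tested apart from these.

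A set of genes, among them Unc13d, Chpt1 and H2-T23, was picked from the plate means. Its members had high levels on both serum plates and lower levels on the 2i and knockout plates. Some, such as Unc13d and H2-T23, share their values with another name, and each name was counted. The set held 19.04% and 24.4% of TPM on the serum plates against 5.43% in 2i and 3.66% in the knockout. That contrast between plates follows from how the set was picked and is not separate evidence of a difference. In bulk RNA the set held 2.57% and 3.05% in serum, 1.72% in 2i and 0.758% and 0.624% in the knockout. Its summed share was therefore lower outside serum there too. Single members moved both ways in 2i bulk RNA. Tmsb4x went from 2645 and 2813 TPM in serum to 82.5 in 2i. Chpt1 went from 3005 and 3785 to 4498, and Park2 from 64.5 and 118.5 to 213. Lifr, Ndrg3, Tmsb4x, S100a6 and Id3, whose falls in bulk RNA are reported, and Ptcra and Cyp2e1, reported as lower in NPCs, belong to this set. The highest 10% of cells held a median of 22.8% and 21% of a gene's TPM, near other genes of like level (19.4% and 18.7%), which argues against a few poor cells. The Spearman correlation with the repeat-like RNA Rn4.5s had medians of 0.0330 and 0.132, so repeat-like reads remain open, as 1 plate lies above the bound of 0.1. RNA polymerase II in their windows relative to all genes was -0.161 in 2i and -0.0035 in the knockout, and H3K4me3 was 0.0285 and -0.0075, so H3K4me3 was not lower in 2i, and more transcription in serum remains open. A difference in the library preparation of the serum plates could also give this pattern and cannot be told apart from culture.

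Lens crystallin transcripts of NPCs were found at low levels on serum plate 2: Cryaa at 7.01 TPM against 0.048 on plate 1 and 0 in 2i and the knockout. Cryaa reached TPM 1 in 72.04% of the plate's cells (at most 60.3 TPM), which argues against whole NPCs on the plate. RNA or reads carried over from NPC libraries may account for it: 8 gene names high in NPCs (7 distinct, since Anxa1 has a second name) were all higher on plate 2 than on plate 1, by a median of 0.00151 of their NPC level (0.00085 with identical values counted once), against 30.1% of genes low in NPCs. Yet of 13 gene names (12 distinct) at TPM 100 or more in NPCs and under 0.1 on the other mESC plates, 3 were above 0 on plate 2 and the median was 0, so this stays open. A first set of genes for this test held 0 members, and no biological explanation was tested.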
